A study of Schizosaccharomyces pombe with 14 samples.

How the data were processed

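Poly(A)+ RNA of Schizosaccharomyces pombe was purified with hot acid phenol, made into stranded paired-end libraries with the Illumina TruSeq mRNA kit and sequenced on a NovaSeq instrument, per the labels' protocols. The 14 samples cross 2 strains, an h- wild type and an h+ strain in which maf1 is replaced by a drug-resistance marker, with 7 times: 0 h in rich medium (YES) and 4, 8, 12, 24, 36 and 48 h in synthetic medium without phosphate (ePMGT). Each sample has 3 replicate experiments, per the series design text, which does not say whether these were separate cultures; p-values therefore measure the spread between these libraries and no wider one. The groups were taken from the labels, and every one of the 42 count columns was used.

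The authors deposited 1 table of counts per gene, and HISAT2 2.1.0, SAMtools, HTSeq 0.10.0, DESeq2 and the genome build ASM294v2 are named in the submitters' processing notes with no role or order. The strand setting, the treatment of reads that map to several places and the annotation version used for counting are not given in these sources. Counts of antisense and overlapping genes, of near-identical copies (tRNA genes, histone genes, ribosomal protein paralogs, M-factor genes) and of subtelomeric families are therefore uncertain. The deposited counts are whole numbers except that 0.5 stands where a 0 would; 19110 of 293538 values (6.51%) are 0.5 and none is 0. They were treated as estimated counts per the file headers and values as deposited, and rounded to whole numbers, 0.5 to 0. The table has 6989 lines, of which 2 share an identifier and were summed, which leaves 6988 identifiers. The authors also deposited 13 tables of comparisons with wild type 0 h, which hold a log2 fold change, an adjusted p-value and a mean normalised signal per gene, made with DESeq2 per the file headers. The mean normalised signal deposited there has 1 value per gene in the 6 wild-type tables and another in the 7 deletion tables, so the authors ran a separate fit for each strain. Symbols came from those tables for 4985 identifiers and from a reference gene table of assembly ASM294v3 for 102, among them symbols that a spreadsheet had turned into dates; 1901 identifiers have no symbol. The reference, which matched 6836 identifiers, is of another assembly than the counts, so no coordinates are given and it served only for names, gene lengths and the order of genes.

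Total counts per library ran from 12157201 to 26359389 in the wild type (median 18088943, n = 21) and from 33249827 to 42808200 in the maf1 deletion (median 36826375, n = 21). Replicates of a sample differed by more than counting error, with a chi-square per degree of freedom of 2.86 to 55.3. Depth, mating type and genotype change together.

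Genes were kept by edgeR's filterByExpr with the 14 groups, which left 6521. With R 4.3.3 and edgeR 4.0.16, library sizes were scaled by TMM and a quasi-likelihood model (glmQLFit, glmQLFTest) with 1 mean per group was fitted to all 42 libraries together, with 28 residual degrees of freedom and a median square root of the tagwise dispersion of 0.0456. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its change at least 2-fold (log2 of at least 1). Every adjusted p of a gene given in the text comes from this model. Standard errors of log2 changes were taken from the model's F statistics. CPM values are counts scaled to a common library size after TMM, computed here from the deposited counts, and are given as mean ± SD over the replicate libraries. Counting intervals and floors (3 counts where a group has none) cover counting error only.

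The comparisons were 8 stage contrasts: the wild type at 4 to 12 h and at 24 to 48 h against 0 h, and the later against the earlier stage; the deletion against the wild type at 0 h, at 4 to 12 h and at 24 to 48 h; the difference between strains in the late response against 0 h, and that in the change from 4 to 12 h to 24 to 48 h. A stage is the mean of its 3 times. The wild type at each of 6 times against 0 h and the deletion against the wild type at each of 7 times were tested too. Fixed before the data were examined were these contrasts, the thresholds, the rule for named genes, the gene lists and all alternatives except those marked as added later.

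The 25 gene lists are phosphate acquisition, inositol pyrophosphate and polyphosphate metabolism, autophagy, cytoplasmic ribosomal proteins, ribosome biogenesis, RNA polymerase I subunits, RNA polymerase III machinery, tRNA processing and modification, translation factors, G1 to S and DNA replication, mitosis and cell separation, histones, core stress response, iron uptake and iron regulation, phospholipid metabolism, nitrogen-starvation response, sexual differentiation, mating-type-specific genes, glycolysis and fermentation, hexose transport and glucose-repressed genes, respiratory chain and ATP synthase, proteasome, thiamine-repressed genes, amino acid biosynthesis, and cell wall synthesis and remodelling. Each was tested in the 8 stage contrasts with limma 3.58.1 camera on log2 CPM (prior count 2), which compares a list with all other genes, with the inter-gene correlation preset at 0.01 and p-values adjusted over the 200 tests. The test was repeated with the correlation estimated from the data. The members of a list called higher or lower were counted with p adjusted over all genes and, again, adjusted over the list alone; the counts were the same in all 200 tests (1662 calls either way).

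The genes named in each stage contrast are maf1, pho1, pho84 and tgp1; the 5 called protein-coding genes with the largest positive and the 5 with the largest negative change that have a standard symbol, a mean of at least 10 CPM and, in direct comparisons of groups, no overlap between the libraries of either side; and, for each list with a camera adjusted p under 0.05, its 2 called members with the largest change in the direction of the list. The tRNA genes as a class, and other genes where marked, were chosen after their values were seen.

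Alternatives were DESeq2 1.42.0 size factors in the same model, library size alone, no low-count filter, DESeq2's Wald test, only the groups compared, replicate number as a block, protein-coding genes only, no fold minimum, an adjusted p under 0.01, and each library left out in turn. Added after the data were seen were thinning of all libraries to the shallowest, the late stage without 48 h, and the deletion against its own 0 h in place of the wild type against its 0 h. Counts of 6521 genes were simulated with the real library sizes and the mean of each gene over all libraries. Changed genes were drawn from well-counted genes only. For the wild type at 24 h against 0 h the model recovered 97 of 100 genes changed 2.5-fold and 100 of 100 changed 4-fold. For the deletion against the wild type at 24 to 48 h it recovered 100 of 100 of each. In either, 1 of 6321 unchanged genes was called. Recovery of genes with few counts, such as many tRNA genes, and the effect of scaling were not covered. In the simulated late comparison of strains camera called the autophagy list, raised 1.5-fold, and none of the 24 other lists. Simulated genes were drawn independently, so this does not show how camera behaves when genes of a list are correlated. Of the genes that would have been named, 1 is not reported here.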

Results

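Poly(A)-selected RNA of fission yeast was measured at 7 times, 0, 4, 8, 12, 24, 36 and 48 h, in a wild-type strain and in a strain that lacks maf1 (SPAC31G5.12c), the gene for a repressor of RNA polymerase III. Each of the 14 samples had 3 replicate libraries. Wild-type libraries held 12157201 to 26359389 counts and deletion libraries 33249827 to 42808200. The 0 h cultures grew in rich medium and all later ones had been moved to synthetic medium without phosphate, so loss of phosphate and change of medium cannot be separated in any comparison with 0 h. The series asks how cells respond to long phosphate starvation and what Maf1 contributes to whether they become quiescent or die. Its title ties the second outcome to aberrant tRNA production.

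The maf1 transcript followed the labels in every library. It stood between 20.9 and 106 CPM in the 21 wild-type libraries and between 1.59 and 7.13 CPM in the 21 deletion libraries. In the wild type it was 22.2 ± 1.11 CPM (SD, n = 3) at 0 h and rose 4.11-fold at 4 to 12 h (log2 2.04, SE 0.07) and 3.77-fold at 24 to 48 h. In the deletion it was 6.78 ± 0.40 CPM at 0 h and 2.86 ± 0.70 CPM (n = 9) at 4 to 12 h, so that against its own 0 h, a comparison added after the data were seen, maf1 changed there by -1.28 at 4 to 12 h and -1.65 at 24 to 48 h. The count table does not show which part of the locus the remaining reads of the deletion strain come from. The strains also differ in mating type. At 4 to 12 h the M-factor gene mfm2 was at 465 ± 157 CPM in the starved h- wild type and 9.91 ± 1.92 CPM in the starved h+ deletion (n = 9 each). For mfm1, mfm2, mfm3 and mam2 the deletion and the mating type cannot be told apart in any comparison of strains below.

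**Figure D1:**
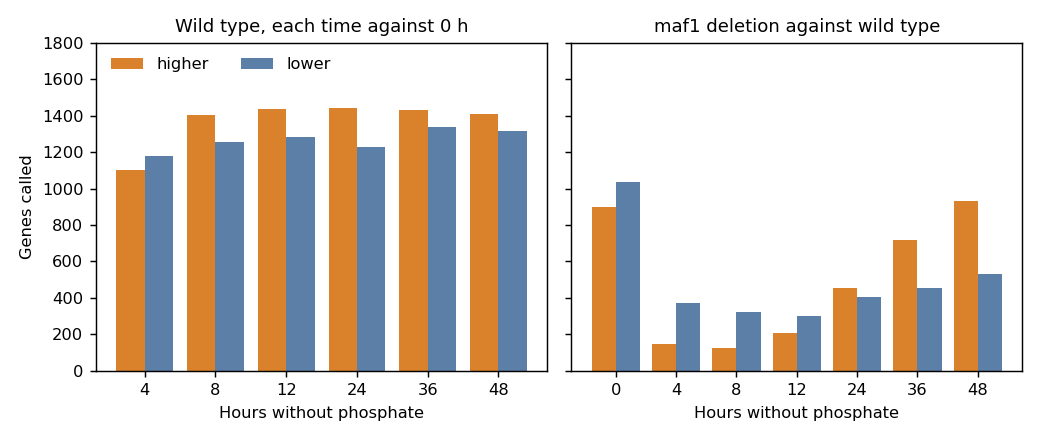
Number of genes called higher and lower (edgeR, adjusted p under 0.05 and at least 2-fold) at each time, for the wild type against its 0 h and for the maf1 deletion against the wild type at the same time. The deletion differed from the wild type in 901 higher and 1036 lower genes at 0 h, in 123 and 321 at 8 h, and in 933 and 533 at 48 h.

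Within 4 to 12 h without phosphate, wild-type cells raised the genes for phosphate acquisition strongly and lowered nearly all ribosomal protein genes. Of 8 phosphate acquisition genes 7 rose and 1 was not called. The acid phosphatase gene pho1 went from 62.1 ± 5.72 CPM (n = 3) to 23660 ± 7472 CPM (n = 9), a 362-fold rise (log2 8.50, SE 0.11), the phosphate transporter gene pho84 rose 19.6-fold and the glycerophosphodiester transporter gene tgp1 32.9-fold. SPBPB2B2.06c, a subtelomeric gene for an extracellular nucleotidase, stood at 0.111 ± 0.067 CPM at 0 h, 9 counts in 3 libraries, and at 2256 ± 1332 CPM in the starved cells. Of 136 cytoplasmic ribosomal protein genes 127 fell and 9 were not called, with a list median of -1.83 (log2); rpp203 changed by -3.52 and rpl1603 by -3.31. Altogether 1275 of 6521 genes rose and 1235 fell, so 50.8% of the calls were higher. With library size alone as the scaling this share was 41.7%.

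Other lists had falling members in the same cells. Ribosome biogenesis genes fell in 49 of 96 cases, rose in 1 and were not called in 46, with utp6 at -2.45 and utp8 at -2.08. Of 11 genes for RNA polymerase I subunits 6 fell, among them nuc1 (-1.55) and ker1 (-1.37). Among 36 translation factor genes 13 fell, with tif5 at -2.62 and tif11 at -2.15, and among 50 genes for tRNA processing and modification 12 fell and 4 rose, with the tRNA isopentenyltransferase gene tit1 at -1.91 and trz2 at -1.71. The 20 genes of the RNA polymerase III machinery went both ways, 3 rising and 4 falling (adjusted p = 0.183 for the list). For the lists that moved, camera gave adjusted p = 4.47e-24 for ribosomal proteins, 1.97e-15 for ribosome biogenesis, 0.000489 for RNA polymerase I, 1.1e-06 for translation factors and 0.00312 for tRNA processing. With an estimated correlation these became adjusted p = 0.475, adjusted p = 0.457, adjusted p = 0.29, adjusted p = 0.457 and adjusted p = 0.457.

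Further lists had rising members at 4 to 12 h. The core stress list had 28 of 44 members higher, with rds1 going from 15.6 ± 2.82 to 2163 ± 437 CPM and the catalase gene ctt1 rising 31.9-fold. Of 19 genes for glycolysis and fermentation 15 rose and 2 fell; gpd3 rose 47.1-fold and eno102 41.7-fold. Hexose transport and glucose-repressed genes rose in 13 of 19 cases and fell in 4, with ght2 up 14.5-fold and ght3 up 22.8-fold. Autophagy genes rose in 13 of 30 cases and fell in 1, led by the kinase gene atg1 (5.17-fold) and the ER-phagy receptor gene epr1 (5.07-fold). For inositol pyrophosphate and polyphosphate metabolism 5 of 8 rose, with siw14 up 4.33-fold and the polyphosphate polymerase gene vtc4 up 3.78-fold. Respiratory chain and ATP synthase genes rose in 13 of 39 cases (log2 1.85 for cox8 and 1.68 for atp16) and histone genes in 6 of 10 (hht3 3.98-fold, hhf3 2.56-fold). Genes of sexual differentiation rose in 12 of 24 cases and fell in 2, with mei2, which encodes a regulator of meiosis, up 18.7-fold and mug14 up 73.2-fold. The M-factor gene mfm1 rose from 0.611 ± 0.238 to 662 ± 635 CPM, ecl3 from 0.235 ± 0.174 to 61.3 ± 16.7 CPM and hry1 from 0.0990 ± 0.0479 to 23.9 ± 15.7 CPM.

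The adjusted p from camera was 0.00104 for phosphate acquisition (adjusted p = 0.457 with an estimated correlation), 2.97e-06 for the stress list (adjusted p = 0.457), and 3.11e-05 for glycolysis (adjusted p = 0.457). Hexose transport had 0.0264 (adjusted p = 0.475) and autophagy 0.000114 (adjusted p = 0.461 with an estimated correlation). The adjusted p was 0.00586 for the pyrophosphate list (adjusted p = 0.366 with an estimated correlation) and 1.29e-06 for respiration (adjusted p = 0.457). Histones and sexual differentiation each had 0.00543 (adjusted p = 0.457 and adjusted p = 0.475 with an estimated correlation). The proteasome list had 0.00188 (adjusted p = 0.491 with an estimated correlation), where 1 of 36 genes, rpn7, rose (log2 1.09). With library size alone as the scaling, the change of rpn7 was 0.906, short of a call. At 24 to 48 h rpn7 was higher by 1.52 in the wild type, but changed by -0.26 within the deletion from its own 0 h.

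Among the steepest falls at 4 to 12 h were meu27 (-6.12), cmt2 (-5.06), mde6 (-5.04), pan5 (-4.82) and fub2 (-4.80). Among these, cmt2 was at 1471 ± 178 CPM in the wild type at 0 h and at 2.70 ± 0.34 CPM in the deletion at 0 h, and fub2 at 396 ± 7.51 and 0.868 ± 0.115 CPM. Within the deletion, from its own 0 h to 4 to 12 h, cmt2 changed by 4.17, fub2 by 4.91, mde6 by 0.34 and meu27 by 0.02, while pan5 kept its call. Short of a call there were siw14 (0.79), tit1 (-0.85), hhf3 (0.02), ght2 (0.55), cox8 (0.96), atp16 (0.89) and rpn7 (0.02). That comparison was added after the data were seen.

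At 24 to 48 h phosphate genes were still above 0 h, while the ribosomal protein genes had come back toward their 0 h level. The level of pho1 was 27030 ± 1288 CPM (n = 9, log2 8.77, SE 0.11), pho84 stood at 7384 ± 640 CPM, 35.1-fold over 0 h, and tgp1 at 2693 ± 235 CPM, 56.3-fold over 0 h. Of the 8 phosphate acquisition genes 7 were higher and 1 not called, with SPBPB2B2.06c at 2154 ± 726 CPM. Of the 136 ribosomal protein genes 13 were called lower, 1 higher and 122 not called, with a list median of -0.37; rpl1002 was at -1.56 and rpl301 at -1.50. In all, 1436 genes were higher and 1312 lower than at 0 h, 52.3% of them higher; with library size alone as the scaling this share was 39.4%, since that choice lowers the median of all genes by 0.27 (log2 shift -0.27).

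Ribosome biogenesis genes were lower than at 0 h in 29 of 96 cases, higher in 2 and not called in 65 (utp8 -2.35, utp6 -2.28), with adjusted p = 4.72e-08 for the list (adjusted p = 0.475 with an estimated correlation). RNA polymerase I genes were lower in 6 of 11 cases (rrn5 -1.61, rpa49 -1.37) and translation factors lower in 9 of 36 and higher in 1 (tif5 -2.41, tif11 -2.15). Autophagy genes were higher in 18 of 30 cases, with atg12 up 9.80-fold and epr1 6.16-fold, and the polyphosphate list in 6 of 8, with siw14 up 6.28-fold and vtc4 4.96-fold. Stress genes were higher in 26 of 44 cases, among them the metallothionein gene zym1 (31.8-fold) and sro1 (25.1-fold). Glycolysis and fermentation genes were higher in 16 of 19 cases and lower in 2; gpd3 stood 79.6-fold and the pyruvate decarboxylase gene pdc201 257-fold over 0 h. Respiratory genes were higher in 16 of 39 cases (cox8 5.86-fold, qcr8 4.32-fold) and genes of sexual differentiation in 11 of 24, with 2 lower (mug14 65.2-fold, mei2 17.4-fold higher). Among the larger rises were also mfm1 (1063 ± 492 CPM), ecl3 (102 ± 4.05 CPM) and hsp3105 (86.7 ± 22.4 CPM, from 0.331 ± 0.097). At the other end stood meu27 (-6.45), pan5 (-5.96), atf31 (-5.41), fub2 (-5.24) and cmt2 (-4.91); within the deletion, from its own 0 h, the last 2 changed by 6.82 and 6.07, and meu27 (-0.44), siw14 (0.79) and qcr8 (0.73) were short of a call. RNA polymerase III genes had 3 higher and 2 lower of 20 (adjusted p = 0.771 for the list).

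For the late stage camera gave adjusted p = 0.000542 for ribosomal proteins (adjusted p = 0.753 with an estimated correlation) and 0.0255 for RNA polymerase I (adjusted p = 0.457). It gave 0.000255 for translation factors (adjusted p = 0.475 with an estimated correlation), 0.00167 for phosphate acquisition (adjusted p = 0.457) and 1.6e-05 for autophagy (adjusted p = 0.457). It gave 0.00584 for the polyphosphate list (adjusted p = 0.366 with an estimated correlation), 2.59e-05 for stress (adjusted p = 0.475) and 4e-05 for glycolysis (adjusted p = 0.457). Respiration had 3e-06 (adjusted p = 0.466) and sexual differentiation 0.0144 (adjusted p = 0.519 with an estimated correlation).

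Between the early and the late stage, ribosomal protein transcripts of wild-type cells rose relative to the other genes. Of the 136 ribosomal protein genes 119 rose and 17 were not called, with a list median of 1.47; rpl3002 went from 7.04 ± 0.90 CPM at 8 h to 136 ± 5.49 CPM at 48 h and rps1402 rose 4.94-fold between the stages. Within the G1 to S and DNA replication list 3 of 42 genes fell and 39 were not called, among the former the kinase gene mik1 (-1.90) and the licensing gene cdt1 (-1.52). Of 42 genes for mitosis and cell separation 6 fell and 36 were not called (adjusted p = 0.212 for the list). The septum glucanase gene eng1 fell from 415 ± 253 to 47.8 ± 19.0 CPM and adg1 from 228 ± 126 to 15.2 ± 13.2 CPM (n = 9 each). In all 432 genes rose and 402 fell, so 51.8% of the calls were higher. With library size alone as the scaling this share was 45.1%.

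Smaller numbers moved in other groups. Ribosome biogenesis genes rose in 2 of 96 cases (rlp7 1.33, ltv1 1.30), tRNA processing genes in 2 of 50 (trm7 at 1.70 and trz2, 2.30-fold), and RNA polymerase III genes in 2 of 20, rpc37 (1.07) and the TFIIIB subunit gene bdp1 (1.04). Of 30 autophagy genes the mitophagy receptor gene atg43 rose (1.06). Without the 48 h libraries, a choice made after the data were seen, rpc37, bdp1 and atg43 were at 0.99, 0.91 and 0.98, short of a call, as they were with library size alone (0.99, 0.95 and 0.97). Among the largest rises were psu2 (61.8-fold), rpl3002 (8.35-fold), pdc201 (7.05-fold), hsp3105 (6.14-fold) and cum1 (5.96-fold); rds1 (-2.69) and the amino acid transporter gene aat1 (-2.63) were among the largest falls. The nitrogen-starvation list had 7 of 23 members lower and 1 higher (adjusted p = 0.112). The phosphate acquisition list had 1 of 8 members higher, 1 lower and 6 not called (adjusted p = 0.34); pho1 (0.27), pho84 (0.85), tgp1 (0.77) and maf1 (-0.12) changed by less than 2-fold. The adjusted p was 1.95e-35 for ribosomal proteins (adjusted p = 0.457 with an estimated correlation), 5.44e-08 for ribosome biogenesis (adjusted p = 0.475) and 0.0107 for autophagy (adjusted p = 0.519). It was 0.0189 for RNA polymerase III (adjusted p = 0.457 with an estimated correlation), 0.0109 for tRNA processing (adjusted p = 0.457) and 0.00589 for G1 to S (adjusted p = 0.457).

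**Figure D2:**
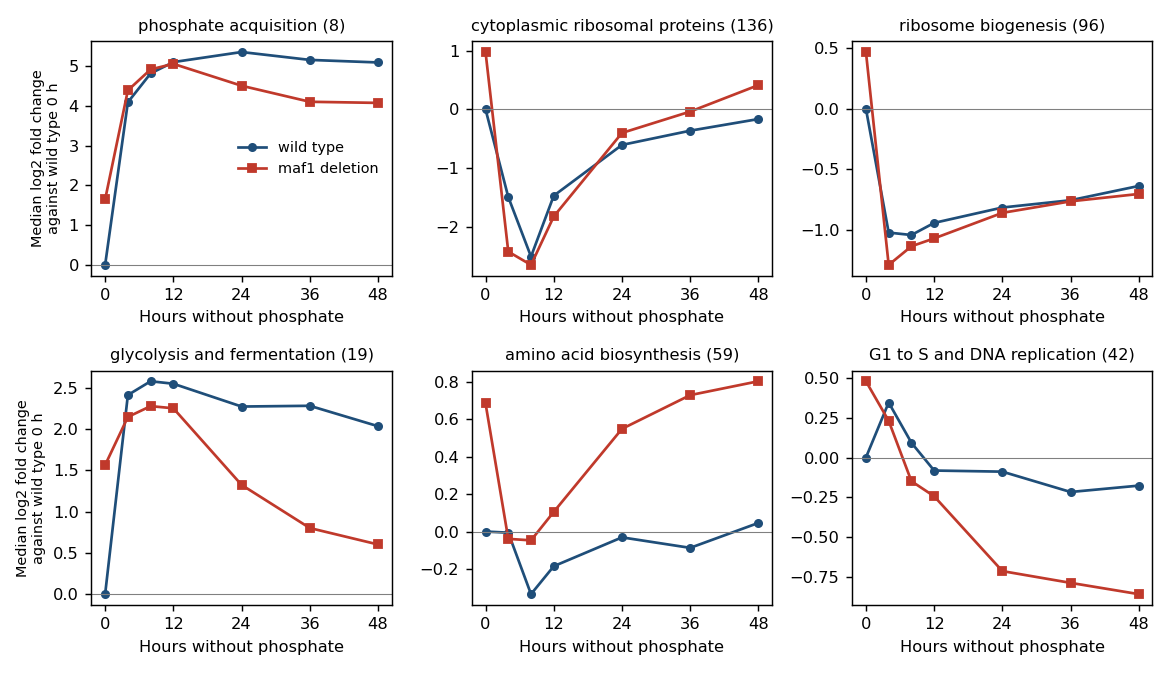
Median log2 change of the members of selected gene lists at each time against the wild type at 0 h, in the wild type and in the maf1 deletion. The ribosomal protein median in the wild type was -2.50 at 8 h and -0.17 at 48 h, and in the deletion -2.65 and 0.41.

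Before starvation the strains already differed, with 901 genes higher and 1036 lower in the deletion. In rich medium pho1 was at 950 ± 155 CPM in the deletion and 62.1 ± 5.72 CPM in the wild type (n = 3 each, log2 3.94, SE 0.09, adjusted p = 5e-30). The level of pho84 was 4.58-fold higher, while tgp1 was lower (13.0 ± 1.72 against 47.8 ± 1.90 CPM). Of the 8 phosphate acquisition genes 5 were higher, 1 lower and 2 not called (adjusted p = 0.0993, and 0.0201 with library size alone). Ribosomal protein genes were higher in 65 of 136 cases, with rps1401 up 10.5-fold and rpl3002 3.08-fold (adjusted p = 2.47e-13; adjusted p = 0.519 with an estimated correlation). Amino acid biosynthesis genes were higher in 19 of 59 cases, among them sua1 (8.02-fold) and ser2 (5.16-fold), with adjusted p = 2.8e-07 for the list (adjusted p = 0.475 with an estimated correlation). Glycolysis genes were higher in 10 of 19 cases and lower in 1, with tdh1 at 10710 ± 837 against 1652 ± 295 CPM and gpm1 6.11-fold up (adjusted p = 0.00589; adjusted p = 0.505 with an estimated correlation).

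The TFIIIB subunit gene brf1 was at 37.4 ± 1.25 CPM in the deletion and 5.33 ± 0.60 CPM in the wild type, and 6 of the 20 RNA polymerase III genes were higher and 1 lower, rpc19 by 2.58-fold. Ribosome biogenesis genes were higher in 13 of 96 cases (rrp17 3.46-fold, nop10 2.95-fold). Translation factor genes were higher in 3 of 36 cases and lower in 1 (tif51 2.84-fold and tef5 2.27-fold higher). G1 to S genes were higher in 10 of 42, with 2 lower (cdc22 3.17-fold and cdc45 2.99-fold higher), and histone genes in 4 of 10 (hht3 2.70-fold, hta2 2.35-fold). Respiratory genes were higher in 3 of 39 cases and lower in 1, with qcr8 and atp16 2.31-fold and 2.27-fold up. Genes of sexual differentiation were lower in 10 of 24 cases and higher in 2, among them the meiotic RNA gene sme2 (-4.67) and mei3 (-2.13). That list had adjusted p = 0.0241 (adjusted p = 0.529 with an estimated correlation), and its call ended among protein-coding genes (0.0542) and with library size alone (0.0717). Mating-type-specific genes were lower in 6 of 10 cases and higher in 1, with mam2 at -5.61 and map2 at -4.20. This list mixes genes of both mating types, so its count does not measure the difference in mating type. Iron uptake genes were lower in 6 of 19 cases and higher in 2 (adjusted p = 0.183). Among the largest gains were pfl7 (35.6-fold), fra3 (19.4-fold), rds1 (15.8-fold) and the malic enzyme gene mae2 (15.5-fold), and among the largest deficits cmt2 (-9.09), fub2 (-8.83), meu27 (-7.18), the fructose bisphosphatase gene fbp1 (-6.41) and mug133 (-5.75). Autophagy genes were lower in 4 of 30 cases and higher in 2, with atg4 at -1.86 and atg43 at -1.46.

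Of the genes called at 0 h 46.5% were higher. With library size alone the share was 26.8% and 494 genes were higher, as that scaling lowers the median of all genes (log2 shift -0.28). With scaling from protein-coding genes alone their counts went from 676 higher and 540 lower to 453 and 660, as all of them moved by a median of -0.17, so the balance of directions at 0 h turns with the scaling. With library size alone tef5, hta2, qcr8 and atp16 missed the 2-fold minimum at 0.90 to 0.95. By camera the adjusted p was 0.000503 for ribosome biogenesis (adjusted p = 0.584 with an estimated correlation), 0.00193 for translation factors (adjusted p = 0.519), 0.00522 for histones (adjusted p = 0.457) and 0.0144 for mating-type genes (adjusted p = 0.457). It was 0.0307 for RNA polymerase III (adjusted p = 0.457 with an estimated correlation) and 0.0297 for G1 to S (adjusted p = 0.457). Respiration had 0.0169 (adjusted p = 0.624) and the proteasome 0.00584 (adjusted p = 0.519 with an estimated correlation). These 4 calls also ended among protein-coding genes alone, at 0.0869, 0.135, 0.19 and 0.125. With library size alone the last 3 ended as well, at 0.051, 0.202 and 0.179.

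At 4 to 12 h of starvation fewer genes separated the strains than at 0 h or at 24 to 48 h. The deletion was higher in 153 genes and lower in 300. The higher genes included 57 tRNA genes, 43 protein-coding genes and 32 ncRNA genes. The lower ones included 202 ncRNA genes and 75 protein-coding genes. Among genes named in advance pho1 (0.05), pho84 (0.19) and tgp1 (0.05) were not called. Apart from maf1 itself (-5.03, SE 0.06) the lower genes included those of mating: mfm2 (-5.51), mfm3 (-4.74), the pheromone receptor gene mam2 (-4.95) and ste6, which encodes a Ras activator (-2.17). Mating-type-specific genes were lower in 6 of 10 cases and genes of sexual differentiation in 5 of 24, with rgs1 at -1.75. Higher were the heat shock gene hsp16 (3076 ± 875 against 858 ± 323 CPM, n = 9 each), wwm3 (3.22-fold) and mfs2 (2.17-fold).

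Some lists differed from the other genes at this stage by camera with no member called. The median was -0.48 for ribosomal proteins (adjusted p = 3.2e-25; adjusted p = 0.475 with an estimated correlation), -0.15 for ribosome biogenesis (adjusted p = 1.03e-06 and adjusted p = 0.475) and -0.19 for translation factors (adjusted p = 4.52e-06 and adjusted p = 0.461). It was 0.24 for amino acid biosynthesis (adjusted p = 1.71e-06; adjusted p = 0.475 with an estimated correlation), 0.16 for autophagy (adjusted p = 0.000434 and adjusted p = 0.475) and 0.15 for respiration (adjusted p = 0.000148 and adjusted p = 0.475). Phospholipid metabolism had 0.11 (adjusted p = 0.00943; adjusted p = 0.457 with an estimated correlation). For mating-type genes and sexual differentiation, with members called, the adjusted p was 0.00558 and 0.000231 (adjusted p = 0.457 for each with an estimated correlation). The lower genes overlapped those lower at 0 h, with 145 shared where 47.7 would be expected of independent sets (Fisher's exact p = 9.42e-42); of the higher genes 28 were shared, 21.1 expected (exact p = 0.122).

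At 24 to 48 h more genes separated the strains again, with 714 higher and 432 lower in the deletion. Of 42 genes of the G1 to S list 10 were lower and 32 not called (adjusted p = 4.25e-06; adjusted p = 0.0514 with an estimated correlation). The replication licensing gene cdt1 was at 1.76 ± 0.77 CPM against 15.1 ± 5.46 CPM in the wild type (n = 9 each), and cdc18 and cdt1 each differed by -3.07. The dUTPase gene dut1 fell from 67.7 ± 2.83 CPM at 0 h to 1.01 ± 0.04 CPM at 48 h in the deletion and stood at 31.2 ± 2.17 CPM in the wild type at 48 h (n = 3 each). Glycolysis and fermentation genes were lower in 10 of 19 cases and higher in 3, with pdc101 at -2.34 (SE 0.04) and the alcohol dehydrogenase gene adh1 at -2.09 (adjusted p = 0.000753; adjusted p = 0.475 with an estimated correlation). Of 59 amino acid biosynthesis genes 19 were higher and 40 not called, led by his3 (2.74) and lys3 (2.59), with adjusted p = 1.59e-10 for the list (adjusted p = 0.457 with an estimated correlation). The level of lys3 reached 1968 ± 73.6 CPM at 48 h against 303 ± 16.6 CPM.

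The level of tgp1 in the deletion was 2178 ± 102 CPM at 12 h and 643 ± 41.9 CPM at 48 h, when the wild type had 2648 ± 75.8 CPM, and at 24 to 48 h it differed by -1.58 (SE 0.04). Of the 8 phosphate acquisition genes 3 were lower and 5 not called (adjusted p = 0.112), and pho1 (-0.41) and pho84 (-0.61) differed by less than 2-fold, with pho1 at 17970 ± 729 against 27880 ± 502 CPM at 48 h.

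**Figure D3:**
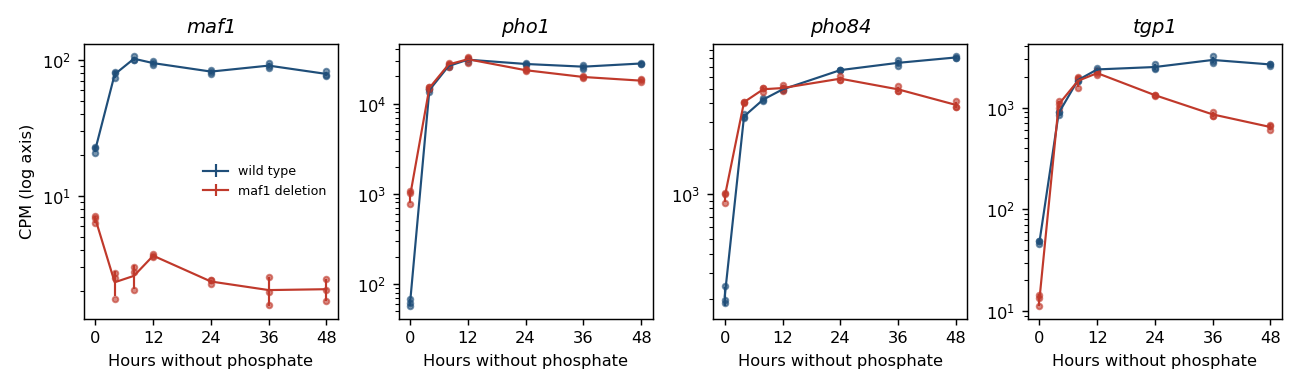
CPM of maf1, pho1, pho84 and tgp1 at each time in the wild type and the maf1 deletion (points are libraries, 3 per time). The deletion starts above the wild type for pho1 and pho84 and below it for maf1 and tgp1, and lies below it for all of them at 48 h.

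Among the largest late differences were ecl1, named for extension of chronological lifespan, at 3756 ± 275 CPM in the deletion and 69.8 ± 10.3 CPM in the wild type at 48 h (n = 3 each). The heme acquisition gene shu1 was at 348 ± 59.3 and 7.98 ± 1.49 CPM. The subtelomeric gene ftm2 (30.9-fold), the flocculin gene pfl7 (24.3-fold) and hry1 (21.4-fold) were also higher. Lower were mfm3 (-8.45), mfm1 (-7.26), maf1 (-5.28) and nmt1, a thiamine synthesis gene that rose in the wild type to 232 ± 35.9 CPM at 48 h and stood at 3.89 ± 0.02 CPM in the deletion. Mating-type-specific genes were lower in 7 of 10 cases. The septum glucanase gene eng1 was lower (-1.27), and 3 of 34 cell wall genes were lower, with agn2 at -2.29 and exg1 at -1.52. Of the ribosomal protein genes rpl1603 (1.30) and rpl1202 (1.02) were higher and 134 not called; rpl1202 was at 0.95 without the 48 h libraries. Among translation factors tif1102 was lower (-1.07). Stress genes were higher in 9 of 44 cases and lower in 1 (adjusted p = 0.341), and hexose transport genes higher in 5 of 19 and lower in 4 (adjusted p = 0.54). Nitrogen-starvation genes were higher in 4 of 23 and lower in 2 (adjusted p = 0.185), and iron genes higher in 1 of 19, shu1, and lower in 3 (adjusted p = 0.997). Of 11 thiamine-repressed genes nmt1 was lower and the others not called (adjusted p = 0.373).

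For the other lists at this stage the adjusted p was 9.06e-09 for ribosomal proteins, median 0.35 (adjusted p = 0.605 with an estimated correlation), 4.37e-05 for respiration, median -0.32 (adjusted p = 0.475), and 2.25e-05 for the proteasome, median -0.36 (adjusted p = 0.457). It was 0.00257 for mitosis (adjusted p = 0.475 with an estimated correlation), 0.0194 for cell wall genes (adjusted p = 0.519), 0.00445 for translation factors (adjusted p = 0.546) and 0.000763 for mating-type genes (adjusted p = 0.457). Of the calls at 4 to 12 h 133 higher and 138 lower were shared with the late stage, where 16.8 and 19.9 would be expected of independent sets (exact p = 1.11e-109 and 2.92e-88). With 0 h the late stage shared 123 higher and 130 lower calls, 98.7 and 68.6 expected (exact p = 0.00682 and 1.37e-14).

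tRNA genes, a class chosen after its values were seen, changed direction between the strains from 0 h to 4 h. From 4 h on, their share of counts in the deletion exceeded that of the wild type by a fold that grew with time. Of 94 tested tRNA genes 38 were lower in the deletion at 0 h, where the share of all counts was 0.171 times that of the wild type for tRNA genes, 0.210 times for snRNA genes, 0.47 times for snoRNA genes and 11.3 times for rRNA genes. The rRNA share was 5.14-fold over the wild type at 4 h, when the tRNA share was 2.88-fold over it. At 4, 8, 12, 24, 36 and 48 h the higher tRNA genes numbered 36, 48, 49, 81, 87 and 89, and the lower ones 4, 7, 5, 4, 3 and 1. The tRNA share of all counts in the deletion was 0.000252% ± 0.000041 (SD, n = 3) at 0 h, 0.00493% ± 0.00032 at 12 h, 0.0201% ± 0.0016 at 24 h and 0.0937% ± 0.0056 at 48 h. In the wild type it was 0.00147% ± 0.00021 at 0 h, 0.0006005% ± 0.000039 at 4 h and 0.00156% ± 0.00016 at 48 h. At 48 h that is 107699 counts against 737 counts in 3 libraries each, a 60.1-fold higher share. At 4 h the deletion had 0.00173% ± 0.00013, so the excess there includes a wild-type level below its own 0 h. Within the wild type, 40 of the 94 tested tRNA genes were lower and 11 higher at 4 to 12 h than at 0 h. At 24 to 48 h 31 were lower and 11 higher than at 0 h in the wild type. Between strains, 88 tRNA genes were higher in the deletion over 24 to 48 h and 3 lower. Of the 88, 10 had no count in the 9 wild-type libraries. With the wild type set to at least 3 counts over those libraries, the median of the 88 was 58.5-fold higher. Over the same stage 20 genes of the RNA polymerase III machinery had a median of 0.05 (adjusted p = 0.417). The 50 genes for tRNA processing had a median of -0.001 (adjusted p = 0.977), with trm7 lower and pus4 higher, both named after their values were seen. Poly(A) selection removes most tRNA, so these counts are of tRNA gene transcripts that passed the selection, and copies of identical sequence cannot be told apart.

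**Figure D4:**
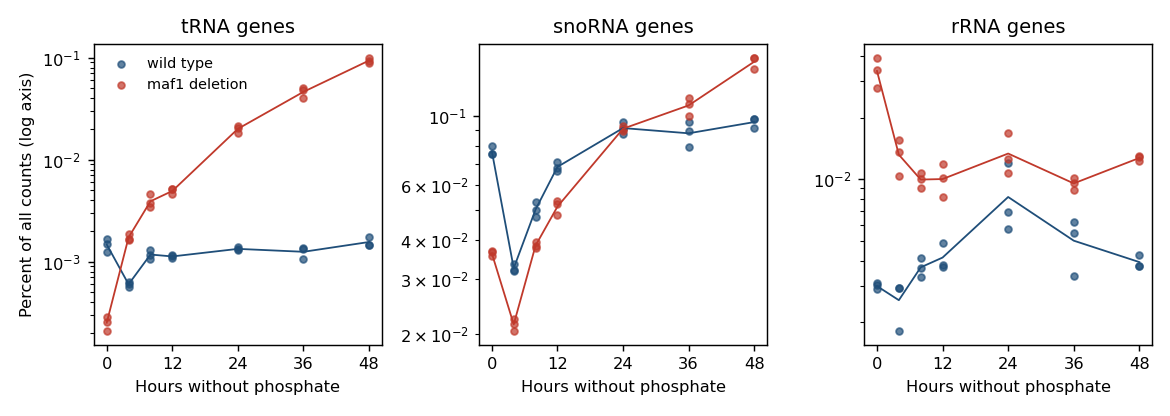
Share of all counts that fall on tRNA, snoRNA and rRNA genes, in percent on a log axis, per library and time in the wild type and the maf1 deletion. For tRNA genes the deletion mean passes from 0.000252% at 0 h to 0.0937% at 48 h. The wild-type mean for tRNA genes is 0.00147% at 0 h, 0.0006005% at 4 h and 0.00156% at 48 h.

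The difference between strains was also tested directly. The late response against 0 h differed in 2491 genes, with 1336 more positive and 1155 more negative in the deletion (53.6% positive, and 70.1% with library size alone, where the median of all genes moves by 0.30 and 723 genes are more negative). Of the protein-coding genes 683 were more positive and 902 more negative, and with scaling from these genes alone 877 and 607, so this balance turns with the scaling too. This difference contains the one at 0 h: the response of pho1 was smaller by a log2 difference of -4.35 (SE 0.10) and that of pho84 by -2.80, from a higher start. SPBPB2B2.06c (-8.73) and SPAC1039.02 (-4.82), both for nucleotidases, and tdh1 (-4.52) and pdc101 (-4.62) were more negative too. In the deletion tdh1 stood at 10710 ± 837 CPM at 0 h and 1011 ± 61.7 CPM at 48 h, and pdc101 at 6712 ± 215 and 979 ± 37.8 CPM (n = 3 each). Among G1 to S genes 18 of 42 were more negative and 1 more positive, with cdt1 at -4.55 and cdc18 at -4.43. More positive were fub2 (12.06), cmt2 (10.99), ftm2 (10.10), fbp1 (7.40) and hsp3102 (7.09), and each of these was lower in the deletion at 0 h (-8.83, -9.09, -5.15, -6.41 and -3.38). Proteasome genes were more negative in 7 of 36 cases and more positive in 1 (rpn7 -1.78, rpn502 -1.51). Camera gave adjusted p = 2.72e-05 for G1 to S (adjusted p = 0.0778 with an estimated correlation), 0.00193 for glycolysis (adjusted p = 0.475) and 2.25e-05 for the proteasome (adjusted p = 0.457). It gave 3.24e-05 for respiration, with 6 of 39 more negative and 1 more positive (adjusted p = 0.475 with an estimated correlation), and 5.92e-05 for translation factors, with 7 of 36 more negative and 1 more positive (adjusted p = 0.475). It gave 3.46e-06 for ribosomal proteins, with 13 of 136 more negative (adjusted p = 0.668 with an estimated correlation), 0.000702 for ribosome biogenesis, with 21 of 96 more negative and 1 more positive (adjusted p = 0.594), and 0.00971 for autophagy, with 8 of 30 more positive and 2 more negative (adjusted p = 0.519).

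The change from the early to the late stage, which uses no 0 h library, differed in 636 genes more positive and 275 more negative in the deletion. Ribosomal protein genes were more positive in 25 of 136 cases, with a median of 0.81 (rpl1603 2.08, rpl3002 1.59), and amino acid genes in 12 of 59 (lys3 2.24, his3 1.99). G1 to S genes were more negative in 8 of 42 (cdc18 -2.50, cdt2 -2.49) and glycolysis genes in 10 of 19, with 3 more positive (pdc101 -2.01, adh1 -1.72). The phosphate list had 3 of 8 more negative, with SPBPB2B2.06c at -2.30 and tgp1 at -1.63. More positive too were shu1 (5.34), ftm2 (3.86), ecl1 (3.85), aat1 (3.29) and hsp3102 (3.26), and more negative mfm3 (-3.71), dut1 (-3.50), nmt1 (-3.30), mfm1 (-3.20) and cmc4 (-3.05). For ribosomal proteins the adjusted p was 3.8e-25 (adjusted p = 0.475 with an estimated correlation) and for amino acid biosynthesis 9.52e-09 (adjusted p = 0.473). For G1 to S it was 4.57e-06 (adjusted p = 0.0514 with an estimated correlation), for glycolysis 0.000136 (adjusted p = 0.461) and for phosphate acquisition 0.0149 (adjusted p = 0.457). It was 6.35e-09 for respiration, where cox13 was more negative at -1.02 (adjusted p = 0.457 with an estimated correlation), 4.52e-06 for the proteasome, median -0.30 (adjusted p = 0.457), and 0.0203 for ribosome biogenesis, with rlp7 at 1.26 and gar2 at 1.19 (adjusted p = 0.698). The call of cox13 ended with DESeq2 size factors and with the Wald test (-0.991 in both), among protein-coding genes (-0.943) and without 48 h (-0.948). Mitosis (cig1 -1.11) had adjusted p = 0.0255 and phospholipid metabolism (plb2 -1.35, plb3 -1.30) 0.0306 (adjusted p = 0.546 and adjusted p = 0.475 with an estimated correlation). Both list calls ended among protein-coding genes, at 0.135 and 0.119, and cig1 was at -0.80 without 48 h.

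Some list calls turned on single libraries or settings, and with an estimated correlation none of the 87 list calls among 200 tests stood (lowest adjusted p = 0.0514). In the late wild type the proteasome list, median 0.30, had adjusted p = 0.0317 and 0.088 without wild type 0 h replicate 2. It had 0.0579 with DESeq2 size factors, 0.479 with library size alone and 0.135 among protein-coding genes. The hexose transport list passed there with library size alone (0.0386). For late against early wild type the proteasome list had 0.0473 and 0.0506 to 0.0628 without any 1 of wild type 4 h replicate 1 or 2, 8 h replicate 2, 12 h replicate 2, 24 h replicate 1 or 3, 36 h replicate 2 or 48 h replicate 3. Between strains at 0 h autophagy had adjusted p = 0.0431 and 0.0745 without wild type 0 h replicate 1, and tRNA processing 0.0564 and 0.0422 without wild type 0 h replicate 2 or 0.0495 without maf1 deletion 0 h replicate 3. At 4 to 12 h G1 to S had adjusted p = 0.0436 and 0.0506 to 0.0519 without wild type 4 h replicate 1, 8 h replicate 1, 12 h replicate 2 or deletion 4 h replicate 1, and 0.051 with library size alone. There the cell wall list had adjusted p = 0.0431 and 0.0507 to 0.0521 without wild type 12 h replicate 2 or deletion 4 h replicate 3, 8 h replicate 2 or 8 h replicate 3, and 0.0503 with library size alone. Mitosis had 0.0615 and 0.0428 to 0.0445 without deletion 8 h replicate 1 or 12 h replicate 3, and 0.0304 among protein-coding genes. At 24 to 48 h sexual differentiation had adjusted p = 0.0536, with 7 of 24 genes lower and 2 higher. It was 0.0435 to 0.0492 without wild type 48 h replicate 1 or deletion 24 h replicate 3, 36 h replicate 2 or 3, or 48 h replicate 2 or 3. It was 0.0443 with DESeq2 size factors, 0.0424 with library size alone and 0.0452 with the replicate number as a block. Autophagy passed at that stage among protein-coding genes (0.0434). For the late response against 0 h, the phosphate acquisition list had adjusted p = 0.0496 for the difference between strains. It was 0.0501 to 0.061 without wild type 24 h replicate 1, 2 or 3, 36 h replicate 1, 2 or 3 or 48 h replicate 1 or 3, or without deletion 24 h replicate 2, 36 h replicate 1 or 3 or 48 h replicate 1, and 0.0616 among protein-coding genes.

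The authors' tables against wild type 0 h gave nearly the same changes. Across the 6517 or 6519 genes in both, which are not independent replicates, the Pearson correlation of log2 changes was 0.9906 to 0.9996. In the 12 comparisons of a starved group 2244 to 2951 genes had the same call at the same thresholds, and in that of the strains at 0 h 1831 genes did. No gene was called in opposite directions in any of the 13 comparisons.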

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

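The tests of thinned libraries, of a batch that holds at every time, of poly(A) selection and of depth for tRNA genes were chosen after the result they measure was seen, as was the alternative of thinning.

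The response of the deletion and that of the wild type were compared by an interaction term in the same model, and each value here is the deletion's response minus the wild type's, in log2. For 24 to 48 h against 0 h 1336 genes were more positive and 1155 more negative. Genes more positive in the deletion were fub2 12.06, cmt2 10.99, ftm2 10.10, fbp1 7.40, hsp3102 7.09, atg4 1.92 and atg43 1.78. More negative were SPBPB2B2.06c -8.73, mfm3 -7.16, mfm1 -7.07, cmc4 -5.82, dut1 -5.78, ecl3 -5.54, SPAC1039.02 -4.82, pdc101 -4.62, cdt1 -4.55, tdh1 -4.52, cdc18 -4.43, pho1 -4.35, maf1 -3.57, rps1401 -3.33, pho84 -2.80, tif51 -1.93, nop10 -1.82, rpn7 -1.78, tef5 -1.73, rrp17 -1.59, rpn502 -1.51, atp16 -1.50, cox8 -1.49 and rps1801 -1.37. The list medians were phosphate acquisition -1.73, autophagy 0.44, ribosomal proteins -0.61, ribosome biogenesis -0.47, translation factors -0.60, G1 to S -0.88, glycolysis -2.42, respiration -0.70 and the proteasome -0.56.

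For the change from 4 to 12 h to 24 to 48 h 636 genes were more positive and 275 more negative. Genes more positive in the deletion were shu1 5.34, ftm2 3.86, ecl1 3.85, aat1 3.29, hsp3102 3.26, lys3 2.24, rpl1603 2.08, his3 1.99, rpl3002 1.59, rlp7 1.26 and gar2 1.19. More negative were mfm3 -3.71, dut1 -3.50, nmt1 -3.30, mfm1 -3.20, cmc4 -3.05, cdc18 -2.50, cdt2 -2.49, SPBPB2B2.06c -2.30, pdc101 -2.01, adh1 -1.72, tgp1 -1.63, plb2 -1.35, plb3 -1.30, cig1 -1.11 and cox13 -1.02. The list medians were phosphate acquisition -0.72, ribosomal proteins 0.81, ribosome biogenesis 0.11, G1 to S -0.38, mitosis -0.22, phospholipid metabolism -0.22, glycolysis -1.12, respiration -0.51, the proteasome -0.30 and amino acid biosynthesis 0.48.

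The first set leans on the 1937 calls between strains at 0 h. Depth differs between the strains, yet with every library thinned to the shallowest 94.7% of those calls were kept in the same direction. A batch between strains that holds at every time would carry the 0 h differences into starvation. The median ratio of the difference at 4 to 12 h to that at 0 h was 0.048 (quartiles -0.128 to 0.222). This argues against such a batch behind most of those calls, but cannot exclude it for a part of them. Of the lower calls 145 were shared by both stages (47.7 expected of independent sets), and of the higher calls 28 (21.1 expected). Wild type 0 h libraries that stand apart from all other groups remain open, with wild type 0 h the extreme group for 1.38 times as many genes as deletion 0 h (1146 against 833). The maf1 deletion, the mating type, a batch at 0 h alone and a lasting batch behind part of the calls cannot be told apart there. Each changes with the strain.

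For the rise of tRNA gene counts in the starved deletion, less complete poly(A) selection would raise the other transcripts without poly(A) tails alike. The highest fold among snoRNA, snRNA and rRNA shares at 48 h was 3.23 against 60.1 for tRNA genes. At 4 h it was 5.14, for rRNA, against 2.88. The snoRNA share was 0.66, 0.766 and 0.745 times that of the wild type at 4, 8 and 12 h. The snRNA share was 0.912, 1.14 and 0.739 times. These classes did not move alike, so at 4 to 12 h this explanation stays open. Transcription running in from neighbours that are themselves raised would show in their counts. The median difference of 163 nearest tested neighbours was -0.133 (quartiles -0.473 to 0.30). Transcription running in with the neighbours' own counts unchanged would not show there. The 10 tRNA genes with most counts, of 187 in the count table, held 54.6% of tRNA counts of the deletion at 48 h. The remaining counts fell on other tRNA genes, so the rise was not confined to those 10. Of the 94 genes that passed the count filter 88 were called higher at 24 to 48 h. A gene could pass that filter through the late deletion libraries alone, so this share is partly built in. Depth does not account for it, as deletion libraries were deeper at 0 h too, where the share was 0.171 times that of the wild type. A rise of tRNA gene transcripts in cells without Maf1, the mating type and the treatment of reads from identical copies stay open. So do transcription running in with the neighbours' own counts unchanged and, for part of the rise, less complete poly(A) selection.

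The return of ribosomal protein transcripts in the wild type, median 1.47 between the stages, was weighed last. The lower of its medians under other scalings was 1.39, so the choice among these scalings does not account for it. Each of them is relative, so a change in the total mRNA of a cell would not show. Genes matched on length and expression moved by a median of 0.195 (quartiles -0.137 to 0.547), which argues against better counting of short transcripts late. A biological recovery during starvation is a hypothesis found and tested on the same data.

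Other splits of the libraries into groups of the same sizes, each refitted on the libraries compared, asked whether grouping by chance gives as many calls, and in each set 1 split, the real one, gave as many. With 100 splits, no other split gave as many calls for the wild type early against 0 h (2486 calls, highest other 256). The same held for late against 0 h (2748 and 3) and late against early (796 and 292). It held for the strains at 4 to 12 h (449 and 68) and at 24 to 48 h (1148 and 813). It held as well for the differences in response against 0 h (2440 and 1766) and between stages (920 and 344). Other splits mix libraries of groups that differ, which widens the spread within groups, and their median was 0 calls in each of these sets. A low count there is partly built in, so these splits do not exclude chance. The 10 splits of 3 against 3 are too few for a share under 0.05. There the real calls were 1871 for the strains at 0 h and, for the wild type at 4, 8, 12, 24, 36 and 48 h against 0 h, 2313, 2654, 2750, 2686, 2794 and 2747. For the strains at the same 6 times they were 511, 432, 497, 815, 1169 and 1465, with a highest other of 0 (edgeR) in each of these 13 sets.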

How the results depend on the processing

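The alternatives of thinning, of the late stage without 48 h and of the deletion against its own 0 h were chosen after the data were seen. Counts of called genes stayed within 1.5 times their value under DESeq2 size factors, DESeq2's Wald test, no low-count filter, only the groups compared, an adjusted p under 0.01, thinning, the late stage without 48 h, the deletion's own 0 h and each library left out (432 values, widest fold 1.12). Deviations of libraries with the same replicate number correlated with a median of 0.0657 (273 pairs, -0.318 to 0.475), against -0.0336 for other numbers, so the number was not taken as a pairing. Yet 39 of 42 libraries correlated best with their own number within their strain, a hint from the data, not the design, of something shared by number. With replicate number as a block all 40 counts stayed within that range as well, and of the calls of genes and lists 1 changed, for sexual differentiation between strains at 24 to 48 h (adjusted p = 0.0452). Of 232 results of named genes 232 kept direction and call with thinning, 231 with DESeq2 size factors, 231 with the Wald test and 224 with library size alone, and 137 of 143 without 48 h. Of 200 list results 87 lost their call with an estimated correlation, 7 with library size alone and 9 among protein-coding genes. Depth was 12157201 to 26359389 counts in the wild type, where 36 of the 88 tRNA genes called at 24 to 48 h had at most 3 counts in 9 libraries.

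Without a fold minimum more genes pass, by construction. Higher and lower were then 2968 and 2822 for the wild type at 4 to 12 h against 0 h, 2945 and 2948 at 24 to 48 h, and 2700 and 2624 late against early. Between strains they were 3105 and 2357 at 0 h, 2461 and 2398 at 4 to 12 h and 2729 and 2842 at 24 to 48 h, and for the differences in response 2563 and 3047 against 0 h and 2437 and 2555 between stages. For the wild type against 0 h they were 2891 and 2696 at 4 h, 2940 and 2755 at 8 h, 2902 and 2819 at 12 h, 2910 and 2818 at 24 h, 2855 and 2844 at 36 h and 2851 and 2830 at 48 h. For the strains they were 2186 and 2084 at 4 h, 1864 and 1746 at 8 h, 1859 and 2015 at 12 h, 2146 and 2354 at 24 h, 2446 and 2518 at 36 h and 2618 and 2638 at 48 h. Shared between 0 h and 4 to 12 h were 1342 higher and 971 lower, between 4 to 12 h and 24 to 48 h 1485 and 1499, and between 0 h and 24 to 48 h 1255 and 984.

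Among protein-coding genes alone fewer genes are tested, by construction, and the scaling, estimated from these genes, shifts them all by nearly the same amount. At 0 h the log2 difference between strains moved by a median of -0.17 (SD 0.004), and 676 higher and 540 lower protein-coding genes became 453 and 660. For the difference in response against 0 h it moved by 0.215 (SD 0.005), and 683 more positive and 902 more negative became 877 and 607, so which direction is more frequent turns with the scaling in both. Higher and lower were 247 and 165 for the wild type late against early, and between strains 40 and 81 at 4 to 12 h and 312 and 200 at 24 to 48 h. They were 294 and 157 for the difference in response between stages. The wild type had 748 lower at 4 h and 899 higher at 8 h. Between strains there were 61 and 151 at 4 h, 41 and 85 at 8 h, 56 and 93 at 12 h, 189 and 165 at 24 h, 327 and 212 at 36 h and 459 and 287 at 48 h.

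With library size alone 494 genes were higher in the deletion at 0 h and 723 more negative for the difference in response against 0 h, as this scaling moves the median of all genes. Against the deletion's own 0 h 55 of 74 named gene results kept direction and call, 10 lost the call and 9 had the other sign, and the cause was not tested. The other sign was at 4 to 12 h in maf1 -1.28, cmt2 4.17, mde6 0.34, fub2 4.91 and meu27 0.0191, the last no detected change (adjusted p = 0.919), and at 24 to 48 h in maf1 -1.65, fub2 6.82, cmt2 6.07 and rpn7 -0.26.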

Other observations

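The test of genes near chromosome ends at 24 to 48 h was written down before its result was seen, and the tests at 0 h and at 4 to 12 h and those of lower genes were chosen afterwards.

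Genes near chromosome ends were over-represented among those higher in the deletion at each stage, and among those lower at 0 h and at 4 to 12 h. Of the 300 protein-coding genes within the 50 nearest each chromosome end, 87 (29.0%) were higher in the deletion at 24 to 48 h, against 204 of 4746 others (4.30%). The odds ratio was 9.09 (Fisher's exact p = 3.34e-41), while 18 genes near ends were lower, against 198 of the others (odds ratio 1.47, exact p = 0.139). At 4 to 12 h 27 were higher, against 16 of the others (odds ratio 29.2, exact p = 2.87e-23), and 11 lower, against 64 (odds ratio 2.78, exact p = 0.00438). At 0 h 61 were higher, against 615 (odds ratio 1.71, exact p = 0.000603), and 65 (21.7%) lower, against 473 (9.97%, exact p = 1.04e-08). In the wild type at 24 to 48 h against 0 h 93 were higher and 63 lower. Reads shared between subtelomeric copies are not resolved in these counts, and no explanation of the excess was tested.

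Counts on ncRNA genes made up 3.21% ± 0.04 (SD, n = 3) of the wild type at 0 h and 1.31% ± 0.02 of the deletion at 0 h. The share on rRNA genes was 11.3-fold higher in the deletion at 0 h and 3.23-fold higher at 48 h. Poly(A) selection removes most rRNA, so these shares are of what passed it.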
